A study of Arabidopsis thaliana with 12 samples.

How the data were processed

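Total RNA of wild-type Arabidopsis thaliana, ecotype Columbia 0, was measured on 12 single-channel arrays, 6 of leaf and 6 of stem. The labels number the samples of each tissue 1 to 6. They do not say that the samples came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

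The authors deposited 1 table of array intensity for 3439 probes and 12 samples. The values are linear and run from 0 to 100, a scale seen in the values themselves. The background correction, the scaling and the meaning of an exact 0 are not given in the sources used here. The highest value of the scale was reached by 3 to 7 probes in each sample, so such probes have only a lower bound there. The tissue of each sample was taken from its label.

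Intensities were converted to log2, with zeros set to missing. A rule set before the data were examined asked for quantile normalization where the medians of the arrays spanned more than 0.2 on the log2 scale. They spanned 1.42, so the arrays were quantile normalized. A probe was tested when it had at least 4 values above 0 in each tissue, which left 2657 probes and set aside 782. Because zeros are missing, the fold of a gene with zeros in 1 tissue depends on how they are treated, and a floor for zeros was 1 of the alternatives. The number of arrays limits the precision.

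Stem was compared with leaf in limma 3.58.1 under R 4.3.3 with statmod 1.5.0, using lmFit and eBayes with a trend and robust variance, two-sided. Benjamini-Hochberg adjustment ran over all tested probes, and an adjusted p under 0.05 counted as past the threshold. Figures were drawn with matplotlib 3.10.9. All log2 differences are stem minus leaf on normalized values. In the scaling used, the median difference over all tested probes was 0.13. That median is small against the differences of the 30 called genes named in the text, so measuring from it could not change a direction. The smallest difference relative to it was 1.14, for DRT101.

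Gene names came from the array's gene table and were updated by locus through a RefSeq table of assembly TAIR10.1, used for names only. Of the probes, 692 had 1 gene, 870 had several genes and 1877 were unnamed here. Names are given only for probes with 1 gene, which cover 691 genes, 598 of them known by locus alone, and 2 single genes were not found in the locus table. A gene with more than 1 probe was taken from the brighter probe.

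The named genes followed a rule fixed before the data were examined. It took the 6 largest rises and the 6 largest falls among genes past the threshold whose leaf and stem values did not overlap. It added, from each list with at least 4 measured genes, the 2 members with the largest absolute difference and any called member that opposed the list. The 21 lists fixed beforehand hold 315 genes. They cover photosynthetic light reactions, the Calvin cycle, photorespiration, lignin, secondary and primary cell wall, xylem regulators, phloem, glucosinolate synthesis and breakdown and flavonoids. They also cover wax and cutin, jasmonate, salicylate, cell division, tubulins, the clock, handling stress, flower organs, guard cells and senescence. Only 6 of these genes had a probe of their own and 5 could be tested, so 19 lists had no measured gene. Symbol-defined families were also planned, and 0 of them had 4 tested members. The reference table holds no descriptions, so ribosomal proteins were sought by symbol in place of description. All other named genes, and 7 gene groups built from gene names, were chosen after the values were seen.

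Lists were tested with cameraPR on the moderated t statistics at a preset correlation of 0.01, in place of camera, which takes no missing values. An estimated correlation, set to 0 where negative, was the alternative. Whether the numbers pair the samples was checked before the calls of the fits were compared. The deviations from the tissue mean of leaf and stem samples of the same number correlated at 0.18 to 0.24 over probes, all above 0.1, against -0.11 to 0.11 for different numbers. By the rule set beforehand the numbers pair the samples; the labels give only the shared number, so the pairing comes from the data. The fit behind the printed values was fixed without a term for the number, and the block is given as an alternative.

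The fit was tested on simulated data of 2657 probes, 200 of them changed, in 10 runs. With independent samples it recovered 28% of 2-fold and 74.1% of 4-fold changes, with 4.39% false calls. With no change it called at most 1 probe, and at most 12 when neighbouring numbers were made to share their deviations. Each probe's deviations were drawn separately, so shifts shared by many probes of a sample were not simulated. The simulation therefore sets no upper limit on false calls in these data. The settings also tried, set before the data were examined, were a block for the number, the deposited values without normalization, median centring, filters on dim or partly missing probes, a floor for zeros, leaving out each number, other variance priors, an unmoderated test, array weights and the mean of a gene's probes. Averaging neighbouring numbers, leaving out numbers 1 and 2, and fits within each pair of numbers were added after the data were seen.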

Results

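The series compared stem tissue with leaf tissue of wild-type Arabidopsis, with 6 samples of each. Of the 3439 probes, 1870 were above 0 in all 12 samples and 99 were at 0 in all 12. Leaf samples had 658 to 785 probes at 0 (19.1 to 22.8%), and stem samples had 479 to 536 (13.9 to 15.6%). The median deposited intensity was 0.104 to 0.154 in leaf and 0.154 to 0.324 in stem, on a scale that ends at 100. The median log2 difference between stem and leaf was therefore 0.62 in the deposited values and 0.13 after quantile normalization.

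MAMI, XERICO, CML30 and AT4G32340 were among the genes that separated stem from leaf most clearly. MAMI (AT5G54110), named as a membrane-associated, mannitol-induced protein, was 7.34-fold higher in stem, and XERICO (AT2G04240), a RING-type zinc finger gene linked to abscisic acid, was 5.86-fold lower. Over the array, 643 of 2657 tested probes passed the threshold, 374 higher and 269 lower in stem. Of these, 301 were at least 2-fold higher and 187 at least 2-fold lower. Among probes with 1 gene, 125 of 510 genes passed, 75 higher and 50 lower. Of the 1870 probes with all 12 values, 306 had no overlap between leaf and stem, 298 of them called, where chance gives 0.216% if the samples are independent. The share of calls that were higher in stem was 58.2%. It was 80.8% (675 higher, 160 lower) in the deposited values and 44.9% (257 higher, 315 lower) with each array centred on its median, and it was 48.2% with zeros at a floor and 44.9% with an unmoderated test, so the balance between rises and falls depends on these choices.

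Neighbouring numbers of a tissue (1 and 2, 3 and 4, 5 and 6) were far more alike than other samples, a grouping seen in the data and absent from the labels. When each such pair counted as 1 sample, 45 probes passed (27 higher, 18 lower), among them 8 genes. The averages of leaf and stem did not overlap for 673 of 2509 probes (26.8%), where chance gives 10% for 3 against 3. The 643 calls describe 12 samples that may hold fewer independent ones.

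**Figure D1:**
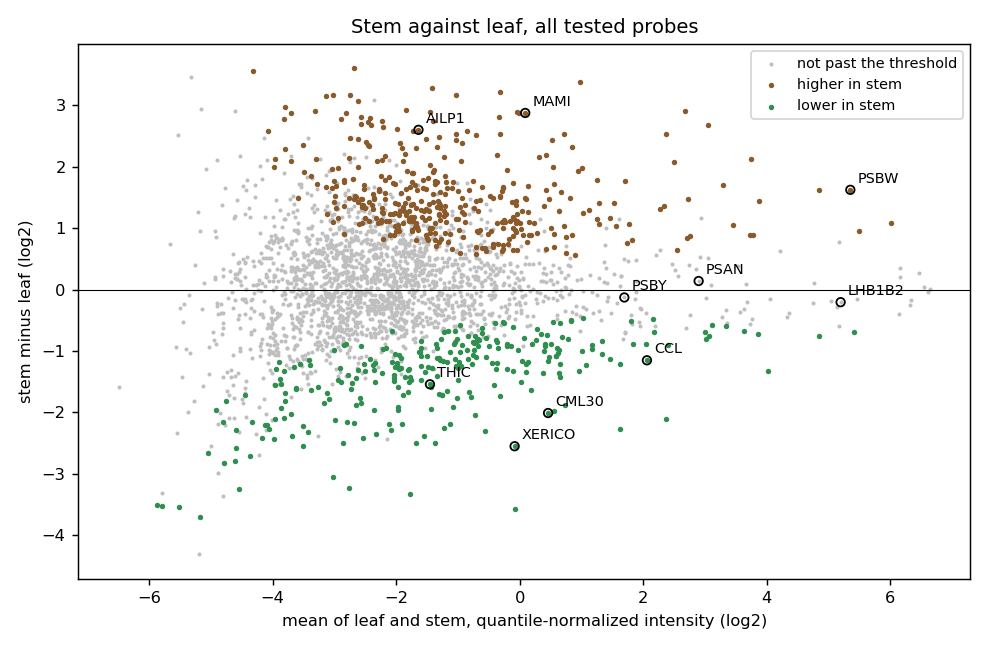
Stem minus leaf difference (log2, vertical axis) against the mean of both tissues (log2 quantile-normalized intensity, horizontal axis); each point is 1 of 2657 tested probes. Brown points mark 374 probes higher and green points 269 probes lower in stem; circles mark named genes, with MAMI at 2.87 and XERICO at -2.55.

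The 6 largest rises with no overlap between tissues were those of AT3G27550, AT4G31930, AT4G30150, MAMI, AT4G17070 and AILP1. AT3G27550 was higher in stem by 3.60 ± 1.202 (log2, SE, adjusted p = 0.041), but its leaf values spread widely, with a mean of -4.48 ± 3.47 (SD, n = 6) against -0.88 ± 0.41 in stem. Its adjusted p was 0.065, 0.074, 0.14 and 0.072 without number 3, 4, 5 or 6 and 0.080 with zeros at a floor, and its difference was 2.41 without number 6. AT4G31930 differed by 3.27 ± 0.39 (SE, adjusted p = 1.1e-04), from -3.06 ± 0.89 (SD, n = 5) in leaf to 0.22 ± 0.50 (n = 6) in stem. MAMI rose from -1.35 ± 0.88 in leaf to 1.53 ± 0.15 in stem (SD, n = 6 each), a difference of 2.87 ± 0.33 (SE, adjusted p = 5.8e-05), and was higher in stem in 6 of 6 numbers. AT4G30150 was higher by 3.07 ± 0.66 (adjusted p = 0.0049), AT4G17070 by 2.68 ± 0.55 (adjusted p = 0.0034; 1.84 with median centring) and AILP1 (AT5G19140), an aluminium-induced-like protein, by 2.60 ± 0.44 (adjusted p = 0.0012). AT4G31930, AT4G30150 and AILP1 were each at 0 in 1 leaf sample, and their differences were 3.63, 3.38 and 2.96 with zeros set to a floor. Within numbers 1 and 2 the difference of AT4G17070 was 0.45, against 3.83 and 3.76 in the other pairs of numbers, that of AT4G30150 was 1.02, against 3.22 and 4.94, and that of AILP1 was 1.01, against 3.40 and 4.12. AT3G27550 differed by 1.06, 1.81 and 7.94 within the 3 pairs, so numbers 5 and 6 carried most of its difference. With neighbouring numbers averaged, AT4G31930 (adjusted p = 0.024) and MAMI (adjusted p = 0.024) kept their call, and the adjusted p of the other 4 lay between 0.054 and 0.18.

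The 6 largest falls were those of AT4G32340, AT4G02040, XERICO, AT1G12800, AT2G35490 and AT1G04420. XERICO had the smallest error, with 1.19 ± 0.21 in leaf and -1.36 ± 0.43 in stem (SD, n = 6 each) and a difference of -2.55 ± 0.21 (SE, adjusted p = 2.6e-06). Its difference was -1.85, -3.00 and -2.80 within the 3 pairs of numbers. AT4G32340 differed by -3.23 ± 0.42 (adjusted p = 1.3e-04) and AT1G12800 by -2.30 ± 0.39 (adjusted p = 0.0011). AT2G35490, a plastid lipid-associated (fibrillin) protein, differed by -2.17 ± 0.37 (adjusted p = 0.0010), and AT1G04420 by -2.15 ± 0.47 (adjusted p = 0.0049). AT1G04420 differed by -0.53 within numbers 1 and 2, against -3.21 and -2.72 in the other pairs, and by -1.37 in the deposited values. AT4G02040 differed by -2.67 ± 0.79 (adjusted p = 0.029) on 5 leaf and 4 stem values, and lost its call with the number as a block (adjusted p = 0.13), in the deposited values (-1.12, adjusted p = 0.29) and with median centring (adjusted p = 0.079). It was at 0 in leaf sample 3 and in stem samples 1 and 2. In deposited values stem sample 5 (0.0474) was above leaf samples 2, 5 and 6 (0.0316, 0.0445 and 0.0341). The lack of overlap of AT4G02040 thus rests on leaving out the leaf zero and on the normalization. With neighbouring numbers averaged, XERICO (adjusted p = 0.013) and AT4G32340 (adjusted p = 0.024) kept their call, and the other 4 had an adjusted p between 0.059 and 0.16.

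**Figure D2:**
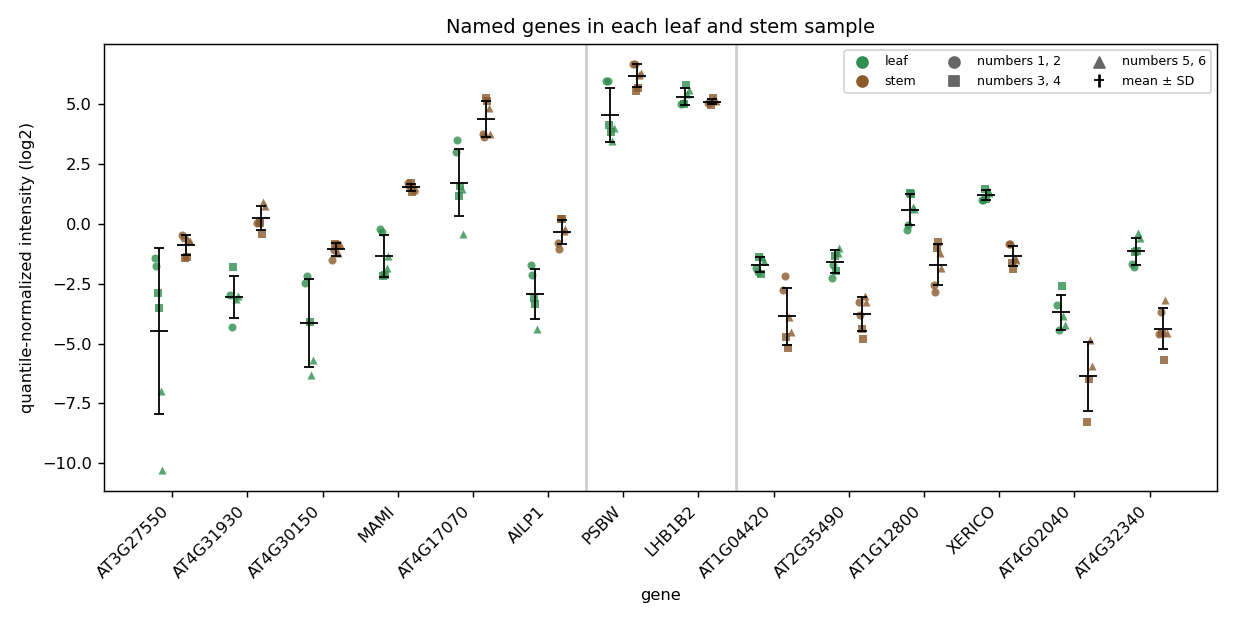
Quantile-normalized intensity (log2, vertical axis) of the 14 rule-named genes (horizontal axis) in leaf (green) and stem (brown); points are samples, their shape gives the pair of numbers, and bars give the mean ± SD. MAMI rises from -1.35 to 1.53 and XERICO falls from 1.19 to -1.36, while leaf values of AT3G27550 spread by 3.47 (SD).

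Of 46 listed genes of the photosynthetic light reactions only 4 could be tested, too few to stand for the pathway. In the scaling used, these 4 did not move together. Of 4 tested members, 1 was higher in stem, 0 were lower and 3 did not pass, with the same counts adjusted over the list alone. PSBW (AT2G30570), a small photosystem II subunit, was higher in stem by 1.62 ± 0.42 (SE, adjusted p = 0.013), from 4.54 ± 1.12 in leaf to 6.16 ± 0.48 in stem (SD, n = 6 each), and in 6 of 6 numbers. Its probe was at the top of the scale in 2 stem samples, numbers 1 and 2, so those values are only lower limits. Within the 3 pairs of numbers PSBW differed by 0.69, 1.63 and 2.55. LHB1B2 (AT2G34420), a light-harvesting antenna protein, differed by -0.21 ± 0.16 (adjusted p = 0.38), PSAN (AT5G64040) of photosystem I by 0.14 ± 0.20 (adjusted p = 0.65) and PSBY (AT1G67740) of photosystem II by -0.13 ± 0.13 (adjusted p = 0.51). The list's median difference was 0.0054 and its mean 0.36 (camera p = 0.84, also with an estimated correlation), and its mean turned to -0.44 (p = 0.078) with each array centred on its median. Under that centring LHB1B2 (-1.22, adjusted p = 0.0040) and PSBY (-0.89, adjusted p = 0.0044) passed as lower in stem, and LHB1B2 also did in the deposited values (-0.65, adjusted p = 0.0030). PSBW lost its call under the same centring (0.96, adjusted p = 0.19), without number 5 (adjusted p = 0.056) or 6 (adjusted p = 0.055) and with neighbouring numbers averaged (adjusted p = 0.14). Of the Calvin cycle list, PRK (AT1G32060), phosphoribulokinase, was the only gene tested, with a difference of -0.096 ± 0.15 (adjusted p = 0.69), and it passed as lower with median centring (-0.78, adjusted p = 0.017). The other 19 lists, lignin and secondary wall included, had no gene on a probe of its own.

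Among the other genes with a symbol, chosen after their values were seen, several with known roles passed the threshold. Lower in stem were CML30 (AT2G15680), a calmodulin-like protein, by -2.01 ± 0.28 (SE, adjusted p = 2.5e-04), and THIC (AT2G29630), which makes the pyrimidine part of thiamine, by -1.54 ± 0.24 (adjusted p = 5.0e-04). CCL (AT3G26740) differed by -1.15 ± 0.21 (adjusted p = 0.0015), or -1.96 with median centring, and PRA1.B3 (AT5G05380) by -1.39 ± 0.28 (adjusted p = 0.0032), or -0.81 in the deposited values. PPDK (AT4G15530), pyruvate orthophosphate dikinase, differed by -1.08 ± 0.25 (adjusted p = 0.0069). LPA19 (AT1G05385), a photosystem II assembly factor, differed by -1.64 ± 0.38 (adjusted p = 0.0071). The drought-induced DI21 (AT4G15910) differed by -1.395 ± 0.34 (adjusted p = 0.0084), and AT-HF (AT4G26900), of histidine synthesis, by -1.93 ± 0.48 (adjusted p = 0.011). CSLA01 (AT4G16590), a cellulose synthase-like gene, differed by -2.21 and IQD22 (AT4G23060), an IQ-domain gene, by -2.15. CSLA01 differed by -0.095 within numbers 1 and 2, against -4.02 and -2.52 in the other pairs. Over the same pairs DI21 differed by -0.46, -2.54 and -1.19, PPDK by -0.55, -1.13 and -1.57 and LPA19 by -0.95, -2.22 and -1.75, and none of these 3 passed in numbers 1 and 2 alone. Higher in stem were the transcription factor genes TCP15 (AT1G69690), by 1.398 ± 0.36 (adjusted p = 0.012), and LAS (AT1G55580), a GRAS regulator of axillary meristems, by 1.33 ± 0.35 (adjusted p = 0.014). DRT101 (AT5G18070) was higher by 1.27, or 2.198 with zeros at a floor, and chr31 (AT1G05490), a chromatin remodelling gene, by 1.28. Within the pairs TCP15 differed by 0.71, 1.23 and 2.26, DRT101 by 0.53, 2.04 and 1.19 and chr31 by 0.94, 0.68 and 2.80. In the deposited values the calls of AT-HF (-1.03), CSLA01 (-1.23), DI21 (-0.72), IQD22 (-1.29), LPA19 (-0.83) and PPDK (-0.62) were lost, and with median centring that of IQD22 (-1.94). CSLA01 and IQD22 each lost their call without any one of numbers 3 to 6. With zeros at a floor IQD22 (adjusted p = 0.059) and chr31 (adjusted p = 0.080) lost it. LAS lost it without number 5 (adjusted p = 0.062), and chr31 without number 5 or 6 (adjusted p = 0.060 and 0.097). With neighbouring numbers averaged, CML30 alone of these kept its call (adjusted p = 0.044).

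The samples did not fall into 2 even groups. Over 793 bright probes, the rank correlation between neighbouring numbers was 0.92 to 0.93 in leaf and 0.98 to 0.99 in stem, and between other stem samples 0.77 to 0.88. Leaf samples 3 to 6 correlated at 0.83 to 0.85 across pairs of numbers. Leaf samples 1 and 2 correlated at 0.65 to 0.69 with them and at 0.61 to 0.77 with stem, whereas leaf samples 3 to 6 correlated at 0.44 to 0.56 with stem. The tissue difference in numbers 1 and 2 correlated across probes with that in numbers 3 and 4 at 0.19 and with that in 5 and 6 at 0.29, against 0.56 between the latter pairs. Of the 643 called probes, 583 had the same sign in all 3 pairs of numbers, and the median size of their difference was 0.88, 1.57 and 1.52 in turn. Without the samples numbered 1 and 2, 859 probes passed, 554 of them among the 643.

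**Figure D3:**
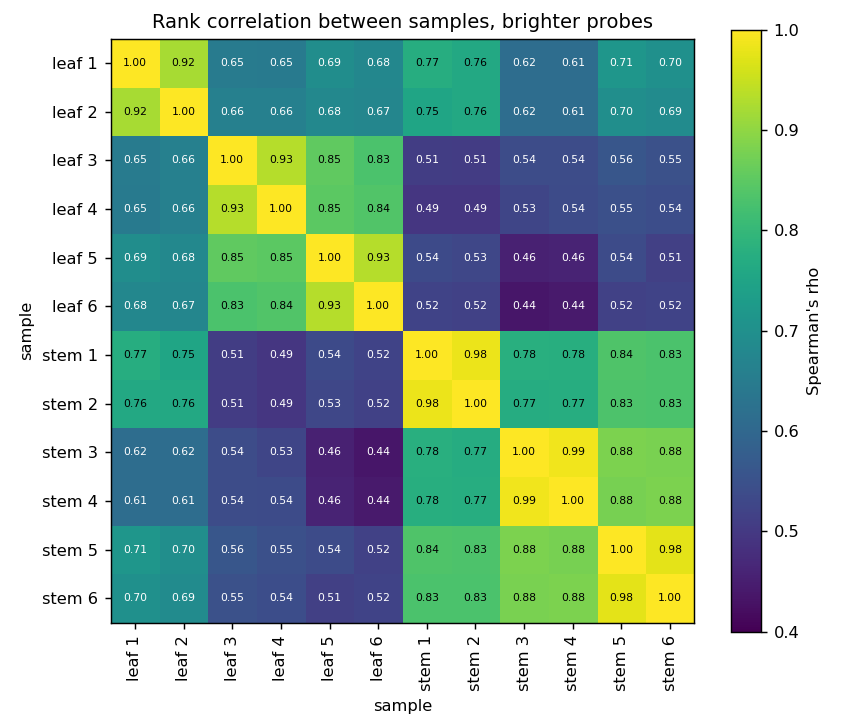
Spearman's rank correlation (colour scale and printed values) between all 12 samples over 793 bright probes; both axes list the samples by tissue and number. Neighbouring numbers form blocks at 0.92 to 0.99, and leaf samples 1 and 2 reach 0.61 to 0.77 with stem.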

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

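The test of stem RNA in leaf samples, of swapped samples and of the scaling was chosen after the result was seen, as were those of repeated samples and of dim spots; the counts over other splits were planned, except those that keep neighbours together.

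Among the named genes, 1 sample stood far from the others of its tissue by the gap to its nearest neighbour. PSB27 (AT1G03600), a photosystem II assembly gene, was at -2.24 in leaf sample 6, while the other leaf samples lay between -0.10 and 0.70. Stem sample 6 was also the lowest of its tissue for this gene, at -0.43 against 0.18 to 1.74 in the others. With 92 groups of samples tested, chance alone sets about 1 in 20 apart in this way.

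Splits of the samples were used to ask whether chance could give the count of probes past the threshold. They would exclude chance only if the 12 samples were independent, which the likeness of neighbouring numbers speaks against. Chance is therefore not excluded. Of 100 drawn splits of the 12 samples into 6 and 6, only the real one (1 split) reached 643 probes, and the highest other gave 1. Of the 32 splits that part all 6 numbered pairs, again only the real 1 did; the highest other gave 5 and set leaf 1, leaf 2 and stem 3 to 6 on one side. Most of these splits part neighbouring numbers, which adds spread within a side. The splits that keep neighbours together number 10, too few for a share under 0.05; the real one gave 643 and the highest other 47.

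Leaf samples 1 and 2 lay between the other leaf samples and stem. A swap is argued against, since stem samples 1 and 2 lay at 0.852 from other leaf (0) to other stem (1), and so is the scaling, since the median rank correlation with stem over the 1383 probes of this test, which no scaling of an array changes, was higher by 0.168 in leaf 1 and 2. Stem RNA in these samples stays open. In linear intensity a mixture needs equal shares of stem signal from stem-high and leaf-high probes. The shares, medians over probes of the mean of both samples, were 0.447 (305 probes) and 0.386 (186 probes). They differed by 0.0613 (95% interval -0.043 to 0.149), within the bound of 0.2. The interval resampled probes and leaves out the spread between samples. Leaf samples 3 to 6 gave shares of -0.014 to 0.0043 from stem-high probes and -0.17 to 0.19 from leaf-high probes. Alone, leaf 1 gave 0.376 and 0.385, and leaf 2 gave 0.416 and 0.384. The shares used quantile-normalized values, where a mixture need not keep them equal, and leaf material of another kind could give equal shares too. The test therefore cannot decide. In further looks, the shares were 0.524 and 0.527 against stem samples 1 and 2, but 0.520 and 0.355 over probes more than 4-fold apart (97 and 27), which is less even. Leaf material of another age or position, which the labels do not describe, was not tested and stays open.

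Neighbouring numbers resembled repeats of one sample, which could make the spread too small. The 45 probes that passed both with 12 samples and with each pair counted once argue against this as the cause of all calls. For the 598 probes that passed only with 12 samples, a smaller spread and a loss of power cannot be told apart; 481 of them were at an unadjusted p under 0.05 with the averages. The 6 averages allow 10 splits, too few for a share under 0.05; the real one (1 split) gave 45 probes and the highest other gave 0.

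Deposited values were higher in stem for most probes. One scale factor per array is argued against, since the median shift differed by 1.08 between brightness classes. A constant offset alone that lifts dim spots in stem arrays is argued against as well, for the mean lift over the 6 numbers. Such an offset adds the same amount to dim and middle spots. The lift was 0.144 in deposited units for 835 probes just above the median brightness and 0.0737 for 835 just below it, a ratio of 1.95 (95% interval 1.71 to 2.24). The interval resampled probes of the mean lift, so it leaves out the spread between arrays. An offset joined with a scale factor per array was not tested and stays open. A lift that depends on brightness in another way, and a broader set of transcripts in stem, were not tested either and stay open.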

How the results depend on the processing

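Averaging neighbouring numbers, the block of 3 pairs, fits within pairs and fits without numbers 1 and 2 were chosen after seeing the data. All 30 called named genes kept their direction in every setting that gave them a value. With the number as a replicate block, 708 probes (415 higher, 293 lower) and 138 genes passed, 598 probes shared with the 643; of the named genes AT4G02040 alone lost its call, while Z-ISO (adjusted p = 0.026), NdhS (adjusted p = 0.047), iqd32 (adjusted p = 0.031) and GH9B11 (adjusted p = 0.049) gained one, none of which passed with neighbours averaged and the pair as a block (adjusted p = 0.13, 0.32, 0.17 and 0.22), and no list call changed.

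The balance of rises and falls moved with the scaling, the zeros and the test. In the deposited values 835 probes passed (675 higher, 160 lower), with 127 genes higher and 26 lower, and 7 of 30 named calls were lost; with median centring 572 passed (257 higher, 315 lower) and 3 were lost. Zeros at a floor gave 612 (295 higher, 317 lower), without the calls of AT3G27550, IQD22 and chr31. The unmoderated test gave 423 probes (190 higher, 233 lower) and 81 genes, 38 of them higher, and 9 named calls were lost (AT3G27550, AT4G02040, AT4G30150, CSLA01, DRT101, LAS, PSBW, TCP15 and chr31). Array weights gave 790, without AT4G02040 and IQD22, and no variance trend 603, without AT3G27550. Z-ISO also passed with array weights (adjusted p = 0.043) and with the filter on all 12 values (adjusted p = 0.046), and GH9B11 with array weights (adjusted p = 0.023) and without number 2 (adjusted p = 0.033). The cause was not tested.

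Leaving out 1 number gave 374 to 655 probes (215 to 370 higher, 159 to 285 lower) and 75 to 128 genes (44 to 81 higher, 31 to 49 lower). The lowest came without number 5 (374); without 3, 4 and 6 there were 422, 404 and 391, and without 1 or 2 there were 655 and 647. With neighbours averaged 45 probes passed (27 higher, 18 lower) and 8 genes (5 higher, 3 lower), and with the pair as a block 90 (59 higher, 31 lower) and 16 genes (12 higher, 4 lower). The block of 3 pairs over all 12 samples gave 888 probes (518 higher, 370 lower) and 158 genes, but it counts neighbouring numbers as separate samples. Averaging cuts the samples to 3 per tissue. In simulation with neighbours sharing deviations it recovered 40.4% of 4-fold changes. The 74.1% of the fit on 12 samples came from independent samples, so these shares are not a like comparison. Within numbers 1 and 2, 466 probes passed (173 lower, 31 genes lower), within 3 and 4, 896 (407 lower), and within 5 and 6, 926 (468 lower). These fits rest on 2 samples per tissue and took probes above 0 in every sample of the fit. The 2 samples are neighbouring numbers, which resembled repeats of one sample. The p-values of these fits measure only the spread between neighbours, so their counts are not a like comparison with the 643.

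The light-reaction mean of 0.36 turned to -0.44 with median centring. None of the other values that turned belonged to a called gene. PSAN was -0.056 as deposited, -0.63 centred, -0.021 with the floor and -0.049 in numbers 3 and 4. NdhS was -0.36 centred. CML41 was 0.27 as deposited, 0.031 without numbers 1 and 2 and 0.40 in 3 and 4. Leaving out 1 number kept its sign, from -0.55 without number 4 to -0.029 without number 2. NTRC was 0.028 as deposited. CHLM was -0.0038 to 0.22 leaving out 1 number (lowest without number 2), -0.070 without numbers 1 and 2 and -0.17 in 5 and 6. ATSPS4F was 0.025 as deposited, 0.0055 with array weights and 0.24 in 5 and 6. In numbers 1 and 2, LHB1B2 was 0.054 and PSB27 -0.43, and PRK was 0.11 and UGT74D1 1.103 in 3 and 4. Median centring gave calls to LHB1B2, PSBY and PRK, and the deposited values to LHB1B2, Z-ISO and iqd32, of which Z-ISO and iqd32 were higher in stem and the rest lower. The cause was not tested. Signal over background is not given in the sources used here, so the limit that dim signal sets is known only through the zeros.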

Other observations

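The 7 gene groups described here were built from gene names after the values were seen. Calmodulin-like and IQ-domain genes had 2 of 4 members lower in stem, CML30 and IQD22, and 0 higher, but the set test gave an adjusted p of 0.47; iqd32 went the other way (1.71 ± 0.72, SE, adjusted p = 0.11, or 0.031 with the number as a block) and was higher when adjusted over the group alone, and CML41 differed by -0.26 ± 0.32. Of 6 photosystem subunits and assembly factors, 1 was higher (PSBW) and 1 lower (LPA19), with an adjusted p of 0.80 for the set; PSB27 differed by 0.96 ± 0.51 (adjusted p = 0.19). Of 4 genes of carbon fixation and central carbon, 1 was lower (PPDK) and 0 were higher (set adjusted p = 0.63), with ATSPS4F, a sucrose phosphate synthase, at -0.10 ± 0.15.

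None of 5 genes of tetrapyrrole, phytol and carotenoid synthesis passed the threshold in limma (set adjusted p = 0.69). Z-ISO and SIRB, which went in opposite directions, were at an unadjusted p under 0.05. Z-ISO (AT1G10830), the carotene isomerase, differed by 1.55 ± 0.56 (adjusted p = 0.055) and was higher in 6 of 6 numbers. With the number as a block it passed (adjusted p = 0.026). Within the 3 pairs of numbers it differed by 3.06, 0.97 and 0.64, and without the samples numbered 1 and 2 by 0.78. SIRB (AT1G50170) differed by -0.84 ± 0.34 (adjusted p = 0.091). CHLM (AT4G25080), of chlorophyll synthesis, differed by 0.15 ± 0.23. Of 3 tested NDH-complex genes 0 passed. At an unadjusted p under 0.05 was 1 of them, CRR21 (AT5G55740), at 1.07 ± 0.49 (adjusted p = 0.13). NdhS (AT4G23890) differed by 0.53 ± 0.29 (adjusted p = 0.20) and passed with the number as a block (adjusted p = 0.047). Of 4 redox genes 0 passed and 0 were at an unadjusted p under 0.05 (set adjusted p = 0.63), with NTRC (AT2G41680) at -0.68 ± 0.35. Of 2 family 9 endoglucanases 0 passed over all probes and 1, GH9B11 (AT2G44560), was lower when adjusted over the group alone, at -1.44 ± 0.51 (adjusted p = 0.054 over all probes, 0.049 with the number as a block). The calls that the block gave to Z-ISO, NdhS, iqd32 and GH9B11 were lost when neighbouring numbers were averaged and their pair was the block (adjusted p = 0.13, 0.32, 0.17 and 0.22). With the pair as a block of 3 over all 12 samples, Z-ISO, NdhS and iqd32 passed (adjusted p = 0.0077, 0.010 and 0.0088) and GH9B11 did not (adjusted p = 0.0504). Without the samples numbered 1 and 2, Z-ISO, NdhS and GH9B11 passed (adjusted p = 0.039, 0.015 and 0.045). Both settings count neighbouring numbers as separate samples. UGT74D1, the 1 family 1 glycosyltransferase tested, differed by -1.02 and did not pass. It ranged from -0.44 without number 1 to -1.71 without number 3, and was -3.23, 1.18 and -2.11 within the 3 pairs of numbers.

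Values above 0 leaned to stem, where every sample had fewer zeros over the array than any leaf sample. The lean may therefore be part of that shift over the whole array, and the meaning of a 0 is not known here. In the deposited values 13 probes were above 0 in all 6 stem samples and at most 1 leaf sample, against 1 probe the other way. By Fisher's exact test 19 probes were more often above 0 in stem and 1 in leaf at an unadjusted p under 0.05, and 0 passed after adjustment. Among probes with 1 gene, AT1G49940 was above 0 in 6 stem samples and 1 leaf sample, and AT4G05070 in 6 leaf samples and 1 stem sample. The lowest stem value of AT1G49940 was 0.0157, close to the floor of 0.0149 used for zeros. The 1 stem value of AT4G05070 above 0 was 0.365, within its leaf range of 0.183 to 0.381. The 45 probes that passed with neighbouring numbers averaged included 3 further genes higher in stem, AT1G17160 (2.43 ± 0.48), AT2G46850 (2.16 ± 0.37) and AT4G20300 (1.65 ± 0.31).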
